A study of Mus musculus with 34 samples.

How the data were processed

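The series holds 34 samples of mouse 3T3-L1 cells, a preadipocyte line, all sequenced. RNA and H3K4me3 ChIP libraries (12 each) cover shLuc and shKdm5ABC cells at day 0, 4 hours and day 2 of adipocyte differentiation, with 2 replicates per group. KDM5A ChIP libraries (6) cover the same times, KDM5C ChIP libraries (2) cover day 2, and there are 2 input samples. Per the labels, cells for RNA and H3K4me3 were transduced with lentiviral shRNA 4 days before induction, for 24 h with polybrene at 6 ug/mL, and no transduction is stated for the KDM5A and KDM5C samples. Differentiation was induced with dexamethasone, insulin, IBMX and serum, and chromatin was fixed with 0.2 mM DSG for 45 min and 1% formaldehyde for 10 min.

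The deposited RNA values are log2 of normalized tags per kb of transcript, per the name of the table. The submitters' processing notes list Bowtie2 (0.12.8 as written there), Subread and DESeq2 for RNA and STAR and HOMER for ChIP, all on mm9. Which size factors or pseudocount the authors used for RNA is not stated. The deposited H3K4me3, KDM5A and KDM5C values are signal, as tags in merged peaks scaled to a common library total (HOMER's default). Each ChIP column consists of whole multiples of a single step (100% of values within 0.1 of a whole number), from which whole reads and library totals were recovered. An automatic check of that recovery covered 4 of the 12 H3K4me3 columns and all KDM5A, KDM5C and input columns, and the recovered reads entered only the edgeR alternative and the depth. Distances to the transcription start site are deposited in bp. The input sample labelled as virus has no column in the tables, so it was not analysed here.

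RefSeq transcripts were named from a reference gene table (17253 of 17515 matched), then from the peak tables (144), and 118 kept their RefSeq ID. A transcript was tested when its log2 value was at least 1 in at least 2 libraries, which left 13534. H3K4me3 (10702 promoter peaks) and KDM5A (87525 peaks) were analysed as log2(tags + 1). Groups came from the sample titles and columns were joined to them by name.

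Groups were compared with limma 3.58.1 in R 4.3.3 (a single fit per assay over all its libraries, mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). The comparisons were knockdown minus shLuc at each time, each later time minus day 0 in shLuc and in the knockdown, and the difference of the knockdown effect between times. RNA and H3K4me3 fits have 6 residual degrees of freedom and the KDM5A fit has 3. The prior degrees of freedom that limma estimated had a median of 4.07 for RNA and 3.74 for H3K4me3 and were infinite for KDM5A. The SE and p of a KDM5A peak therefore rest on the trend of spread over all peaks, and not on the spread of that peak. The smallest 2-sided p of an exact permutation test of 2 against 2 libraries is 0.333, so single genes were tested only through the shared fit. SE is the error of the fitted difference and SD the spread of the 2 libraries. Replicate numbers were checked for pairing by correlating the difference between replicates across features. The correlation was 0.381 to 0.657 over 15 pairs of RNA groups, 0.504 to 0.790 for H3K4me3 and 0.0470 to 0.333 over 3 pairs for KDM5A. RNA and H3K4me3 results are therefore also given with the replicate number as a block.

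26 gene lists (659 symbols, 549 of them measured in RNA) were fixed before the data were examined. They were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A list's value is the mean log2 fold change of its measured genes. KDM5A occupancy of a promoter is the sum of the mean tags of the KDM5A peaks that overlap its H3K4me3 peak by at least 1 bp, and bound promoters are the top 25% by day 2 tags. Shares of lists in the top 25% of genes, by the highest KDM5A peak within 1000 bp of the start site, were compared by Fisher's exact test, two-sided, adjusted over the lists.

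Named genes followed a rule also set before the data were examined. It covers the Kdm5 genes, up to 4 members with the smallest p in each list past the threshold, or the 2 members at the highest level where none was past it. It also covers the 5 highest and 5 lowest RNA changes among called genes with a mean log2 level of at least 3 and no overlap of groups, and the 3 highest and 3 lowest ChIP peaks with at least 20 tags. The promoters of named day 2 genes complete it.

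Library totals recovered from the steps ranged from 8.37M to 13.6M tags for H3K4me3, 3.87M to 17.6M for KDM5A and 2.95M to 8.13M for KDM5C. The RNA table holds no counts, so the depth of its libraries is not known. Spread between replicates exceeded counting error, with a chi-square per degree of freedom of 10.2 to 15.5 for H3K4me3 and 4.17 to 5.40 for KDM5A. Intervals on peak shares cover counting error only. On simulated data of the same size, the limma fit recovered 66% of RNA changes of 1 on the log2 scale at day 2 and 98% of changes of 2. For H3K4me3 it recovered 88% and 100%. The KDM5A fit recovered 0% of changes at every simulated size, up to 3. Camera called 20 of 20 lists shifted by 0.5 and 0 of 20 unshifted lists, as tested on simulated data. The simulated genes varied independently and lists were drawn at random. The simulation therefore cannot show how camera at the preset correlation behaves for lists of correlated genes.

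Alternatives were other scalings (quantile normalization, medians set equal), other filters and pseudocounts, a fit without the trend, a fit on the compared groups alone, a fold change threshold, the replicate block and leaving out each library. edgeR 4.0.16 (quasi-likelihood test) was run on the recovered ChIP reads. It shares the library totals with the limma fit, so it tests the error model and not the scaling. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.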

Results

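All 3 targets of the knockdown were lower in shKdm5ABC cells at each time. Kdm5c fell by 1.40 on the log2 scale at day 0 (SE 0.18, adjusted p 0.00629), which left 38.0% of the shLuc level, and 39.7% and 39.2% were left at 4 hours and day 2. Kdm5a was left at 50.7%, 58.1% and 53.4% (adjusted p 0.00714, 0.0216 and 0.00424), and Kdm5b at 60.8%, 60.2% and 63.9% (adjusted p 0.0101, 0.0112 and 0.00664). These genes encode demethylases of histone H3 lysine 4. Kdm5d had no tested transcript. Kdm5b also fell with differentiation in shLuc cells, by 0.73 at 4 hours and 0.88 at day 2 (adjusted p 3.64e-04 and 4.82e-05). Each group has 2 libraries. The sample titles number the replicates as experiments, but whether these are independent cultures is not stated. Each p comes from the shared fit over all groups and holds for these samples only.

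**Figure D1:**
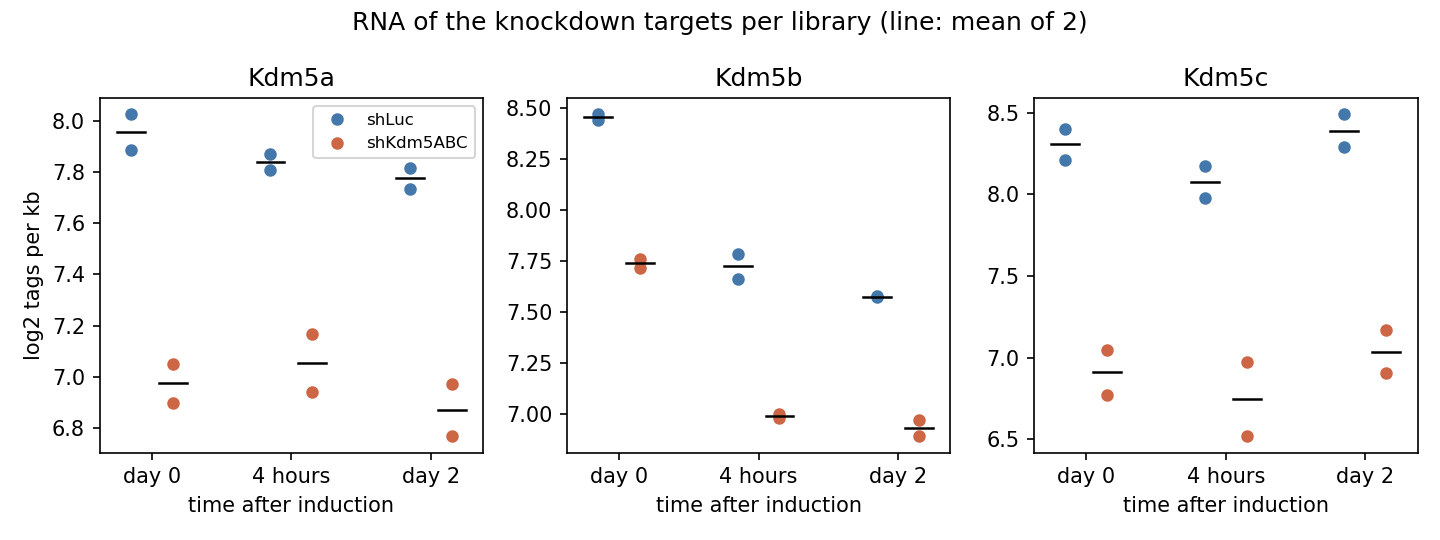
RNA level (log2 tags per kb) of Kdm5a, Kdm5b and Kdm5c in each of the 12 RNA libraries by time and shRNA, points for libraries and lines for means of 2. At day 0 the mean of Kdm5c was 8.31 in shLuc and 6.91 in shKdm5ABC.

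In shLuc cells, genes that answer glucocorticoid and cAMP rose within 4 hours of induction. Dusp1, a phosphatase that ends MAP kinase signalling, rose from 6.21 (SD 0.06) to 11.23 (SD 0.25) log2 tags per kb, and Errfi1 and Fkbp5 rose by 4.20 and 3.31 (SE 0.21 and 0.17). Of 25 measured genes of the immediate-early, cAMP and glucocorticoid list, 22 rose and 0 fell, 22 and 0 adjusted over the list alone. Myc rose by 3.48 (SE 0.44) and the adipogenic factor Klf5 by 3.44 (SE 0.15). Vegfa and Ldha were among 16 of 23 glycolysis and hypoxia genes that rose, and Hsph1 (3.64, SE 0.27) among 9 of 14 heat shock genes. Insig1 (-2.24, SE 0.33) and Fdps were among 15 of 23 cholesterol synthesis genes that fell, while Pmvk rose by 4.52. Fgl2 (6.36), Ramp3 (6.35) and Vdr (5.58) rose the most under the naming rule, and Zfp41 (-4.47) and Kif21b (-4.27) fell the most. Ifit2 (-3.83) and Irgm1 (-2.61) were among 27 of 30 interferon genes that fell, 28 adjusted over the list alone. In all, limma called 5724 genes at 4 hours, 2796 up and 2928 down, or 7915 with the replicate block.

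By camera, 8 fixed lists were past the threshold at 4 hours in shLuc cells. The immediate-early list had a mean of 2.53 (adjusted p 1.68e-13, 0.409 with an estimated correlation), the interferon list -2.01 (adjusted p 1.99e-11, 0.646 with an estimated correlation) and the heat shock list 1.02 (adjusted p 7.42e-04, 0.409 with an estimated correlation). Glycolysis (0.73, adjusted p 1.47e-04) and cholesterol synthesis (-0.74, adjusted p 0.00647) both had an adjusted p of 0.730 with an estimated correlation. Inflammatory genes (9 of 21 rose, 4 fell, adjusted p 0.0460) and oxidative phosphorylation genes (9 of 29 rose, 1 fell, adjusted p 0.0370) also had 0.730 with an estimated correlation, and ribosomal genes (1 of 35 rose, adjusted p 0.0370) had 0.889 with an estimated correlation. Of 50 replication genes 7 rose and 10 fell, and of 46 mitosis genes 3 rose and 8 fell.

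By day 2 the cells had turned on both the cell cycle and the adipocyte programme. Rrm2, which makes deoxynucleotides, rose from 6.00 (SD 0.15) to 9.65 (SD 0.14), and Cdc45 and Mcm5 rose by 3.31 and 2.65 (SE 0.19 and 0.19). Of 50 replication genes 47 rose, and 46 of 46 mitosis genes rose, with Cdc20 and Birc5 up by 2.79 and 3.15 (SE 0.16 and 0.19). Cidec, a lipid droplet protein, rose by 8.28 (SE 0.83), Retn by 6.96 (SE 0.53), Lipe by 5.58 (SE 0.35) and Cebpa by 4.12 (SE 0.22). Of 33 adipocyte genes 27 rose and 1 fell, and 16 of 23 adipogenic factors rose and 4 fell. Cycs and Cyc1 were among 29 of 29 oxidative phosphorylation genes that rose. Thbs2 (-5.21, SE 0.19) and Lox (-4.74, SE 0.20) were among 25 of 33 matrix genes that fell, Pdgfrb and Dlk1 among 13 of 17 preadipocyte genes, and Acta2 (-6.22, SE 0.55) among 8 of 12 muscle genes. In the CDK inhibitor and p53 list 14 of 22 fell, among them Cdkn2b (-2.86, SE 0.29), and 12 of 21 inflammatory genes fell, among them Csf1 (-3.93, SE 0.18). Of 6 measured neuronal markers 4 fell, of 9 histone genes 6 rose, of 35 ribosomal genes 10 rose and of 9 macrophage markers 5 fell.

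Interferon genes fell between day 0 and day 2 in shLuc cells. Ifit3, an antiviral effector, fell from 9.12 (SD 0.51) to 1.96 (SD 0.12), and Isg15 and Stat2 fell by 5.09 and 3.94 on the log2 scale (SE 0.23 and 0.14). Of 30 measured members 29 fell and 0 rose, 29 and 0 adjusted over the list alone. In all, limma called 7441 genes between day 0 and day 2, 3673 up and 3768 down, or 9034 with the replicate block. By camera the mean changes of the replication (1.62, adjusted p 2.29e-16), mitosis (2.41, adjusted p 5.29e-19), adipocyte (3.39, adjusted p 5.36e-10) and interferon (-4.31, adjusted p 3.85e-16) lists were past the threshold. With an estimated correlation the adjusted p values were 0.143, 0.143, 0.289 and 0.143. In shKdm5ABC cells the same interval gave 6114 calls, 2983 up and 3131 down. There 41 of 50 replication genes rose (mean 1.12), 44 of 46 mitosis genes (mean 1.98) and 26 of 33 adipocyte genes (mean 2.55), and oxidative phosphorylation rose in 29 of 29.

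At day 0 interferon and stress response genes were lower in shKdm5ABC than in shLuc cells. There is no untransduced RNA sample, so effects of the knockdown and of the shLuc virus on interferon genes cannot be told apart. Isg15 was 10.11 (SD 0.31) in shLuc and 7.56 (SD 0.24) in shKdm5ABC libraries, a change of -2.56 (SE 0.23, adjusted p 0.00164). Rsad2 changed by -3.44 (SE 0.31) and Ifit3 by -2.50 (SE 0.28). Of 30 measured interferon genes 16 fell, 28 adjusted over the list alone, and all 30 had a lower mean (list mean -1.70, adjusted p 8.02e-38, 0.0792 with an estimated correlation). Of 22 unfolded protein and integrated stress response genes 8 fell, 11 adjusted over the list alone (mean -0.70, adjusted p 5.00e-12, 0.0792 with an estimated correlation). They included Ddit3 (-1.70, SE 0.19), Chac1 (-2.28, SE 0.24), which degrades glutathione, and Atf5 (-1.38, SE 0.13), and Trib3 fell by 2.72 (SE 0.31). Klf5 rose by 1.22 (SE 0.15), Cebpa by 1.09 (SE 0.22) and the cyclin Ccnd3 by 0.59 (SE 0.12). The highest changes were Cntfr (2.62), Ubd (2.56) and Adh1 (2.06), and Cdsn was lowest at -3.67 (SE 0.51).

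No replication or mitosis gene was called by limma at day 0 (0 of 50 and 0 of 46, also 0 adjusted over the list alone). With the replicate block 5 and 12 fell, and over all genes 1725 had an unadjusted p under 0.05. Top2a, for example, changed by -0.69 (SE 0.26, adjusted p 0.285). The mitosis list had a mean of -0.43 (adjusted p 2.24e-11, 0.639 with an estimated correlation), the replication list -0.14 (adjusted p 0.0244, 0.935 with an estimated correlation) and the adipocyte list 0.48 (adjusted p 0.00652, 0.935 with an estimated correlation). The 3 measured endothelial markers, Egfl7 among them (0.96, SE 0.30), had a mean of 0.74 (adjusted p 0.0320, 0.246 with an estimated correlation). In all, 204 genes were called at day 0, 82 up and 122 down. With the replicate block 1277 were called, 593 up and 684 down, and 11 with only the compared groups. The number rested on every library. It was 72 without shLuc replicate 1, 13 without shLuc replicate 2, 41 without shKdm5ABC replicate 1 and 35 without shKdm5ABC replicate 2.

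At 4 hours interferon and stress response genes were lower in shKdm5ABC cells too. Isg15 fell by 1.71 (SE 0.23) and Stat2, a transducer of interferon signals, by 0.92 (SE 0.14). Of 30 interferon genes 11 fell, 22 adjusted over the list alone (mean -1.25, adjusted p 3.25e-24, 0.244 with an estimated correlation). Psat1 (-0.89, SE 0.13) and Phgdh (-0.99, SE 0.15), which make serine, were among 5 of 22 stress response genes that fell, 8 adjusted over the list alone (mean -0.38, adjusted p 4.66e-06, 0.332 with an estimated correlation). Bub1b (-0.90, SE 0.18) was the single called gene of 46 in the mitosis list (mean -0.29, adjusted p 3.60e-05, 0.961 with an estimated correlation). Ribosomal genes had a mean of -0.10 with 0 of 35 called by limma (adjusted p 0.0272, 0.961 with an estimated correlation, and 3 fell with the block). Angpt2, an angiogenic ligand, rose by 3.46 (SE 0.33), Lsp1 by 2.21 (SE 0.46) and Mamstr by 2.06 (SE 0.20), and Cdsn (-3.14), Ifi44 (-2.24) and Mmp13 (-2.12) were lowest. In all, 195 genes were called, 108 up and 87 down, or 1310 with the block (620 up, 690 down), and 0 by limma with only the compared groups (1342 with an unadjusted p under 0.05). The number was 11 without shLuc replicate 1, 36 without shLuc replicate 2, 26 without shKdm5ABC replicate 1 and 33 without shKdm5ABC replicate 2.

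At day 2 cell cycle genes were lower in shKdm5ABC than in shLuc cells. Cdc20, which activates the anaphase-promoting complex, was 8.75 (SD 0.19) in shLuc and 7.66 (SD 0.05) in shKdm5ABC libraries, a change of -1.09 (SE 0.16, adjusted p 0.00470). Mad2l1 fell by 0.89 (SE 0.14) and Cdca8 by 1.04 (SE 0.17). Of 46 mitosis genes 25 fell and 0 rose, 40 and 0 adjusted over the list alone, and all 46 had a lower mean (list mean -0.87, adjusted p 1.17e-21, 0.214 with an estimated correlation). Tyms (-0.95, SE 0.18), Gins1 (-1.04, SE 0.20) and Rfc4 (-0.84, SE 0.17) were among 21 of 50 replication genes that fell, 40 adjusted over the list alone, with 0 that rose (mean -0.63, adjusted p 3.24e-19, 0.155 with an estimated correlation). With the replicate block 44 mitosis and 43 replication genes fell. In the G1/S list E2f2 (-1.23, SE 0.29), Cdc25a (-0.64, SE 0.14) and Tfdp1 (-0.63, SE 0.12) were among 4 of 21 that fell, 7 adjusted over the list alone, and Rbl2 rose by 0.49 (SE 0.13) (mean -0.31, adjusted p 0.00789, 0.214 with an estimated correlation). The CDK inhibitors Cdkn2b (6.58 in shLuc and 8.08 in shKdm5ABC, SE of the difference 0.29) and Cdkn1b (0.67, SE 0.15) and the death receptor Fas (0.66, SE 0.17) were the 3 of 22 in their list that rose, 6 adjusted over the list alone (mean 0.24, adjusted p 0.0718).

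**Figure D2:**
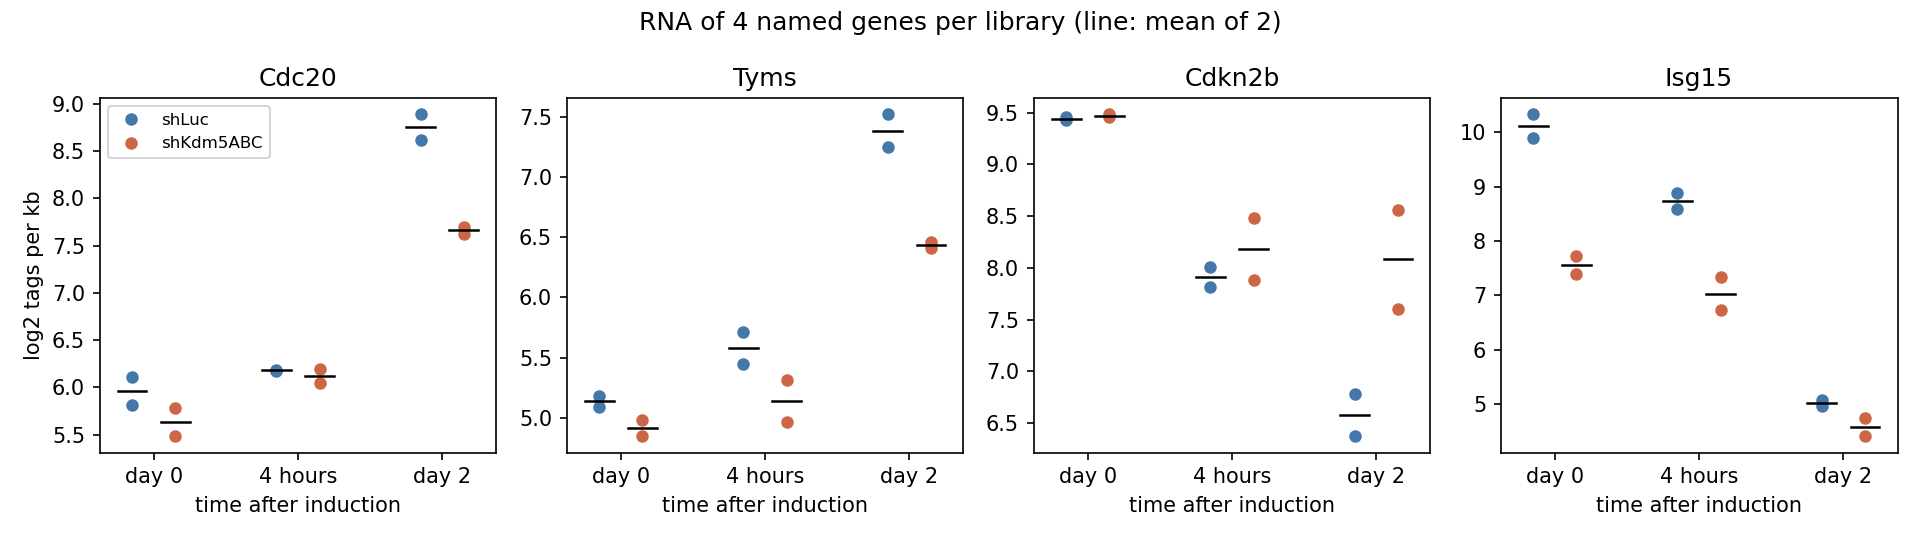
RNA level (log2 tags per kb) of Cdc20, Tyms, Cdkn2b and Isg15 in each RNA library by time and shRNA, with lines for means of 2. At day 2 the mean of Tyms was 7.39 in shLuc and 6.44 in shKdm5ABC.

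Among adipocyte genes at day 2, Elovl6, a fatty acid elongase, rose by 0.79 (SE 0.19). It was the single called gene of 33 adipocyte genes (0 adjusted over the list alone by limma, while 1 rose and 9 fell with the block). The list mean was -0.36 (adjusted p 0.00890, 0.627 with an estimated correlation). That mean was -0.15 (adjusted p 0.22) without shLuc replicate 2 and -0.032 (adjusted p 0.566) without shKdm5ABC replicate 1. Ebf1 (0.73, SE 0.15) and Klf5 (0.65, SE 0.15) were the 2 of 23 adipogenic factors that rose, 2 adjusted over the list alone, with a list mean of 0.035 (adjusted p 0.775) that was -0.0057 without shKdm5ABC replicate 2. Pdgfra (1.19, SE 0.26), a receptor of preadipocytes, and Wnt6 (1.72, SE 0.43) were the 2 of 17 preadipocyte genes that rose, 5 adjusted over the list alone (mean 0.55, adjusted p 6.85e-04, 0.155 with an estimated correlation). Fbn1 (1.97, SE 0.33), Timp2 (1.25, SE 0.19) and Lox (1.23, SE 0.20) were among 7 of 33 matrix genes that rose, 10 adjusted over the list alone (mean 0.49, adjusted p 4.56e-04, 0.30 with an estimated correlation).

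Other groups moved at day 2 as well. Cxcl5 (2.13, SE 0.45) and Vcam1 (1.32, SE 0.20) were among 6 of 21 inflammatory genes that rose, 8 adjusted over the list alone, while Saa3 fell by 0.99 (SE 0.24) (mean 0.46, adjusted p 0.00270, 0.404 with an estimated correlation). Tsc22d3 (0.94, SE 0.16) and Jun (0.95, SE 0.18) were among 5 of 25 immediate-early genes that rose, 6 adjusted over the list alone (mean 0.28, adjusted p 0.0180, 0.615 with an estimated correlation). Ndufa4 (-0.50, SE 0.12) and Cycs (-0.62, SE 0.16) were the 2 of 29 oxidative phosphorylation genes that fell, 12 adjusted over the list alone and 16 with the block, and all 29 had a lower mean (list mean -0.29, adjusted p 4.01e-07, 0.30 with an estimated correlation). Lss (-0.94, SE 0.19) and Insig1 (-1.23, SE 0.33) fell and Tm7sf2 rose by 0.77 (SE 0.18) in the cholesterol list (mean -0.38, adjusted p 0.0149, 0.627 with an estimated correlation). Shmt2 and Atf5 fell by 0.44 and 0.48 (SE 0.11 and 0.13) among 22 stress response genes, 4 adjusted over the list alone (mean -0.41, adjusted p 2.07e-05, 0.214 with an estimated correlation). The interferon list had a mean of 0.09 (adjusted p 0.362) at day 2. Germline (0 of 12), neuronal (0 of 6), muscle (0 of 12), endothelial (0 of 3), histone (0 of 9) and ribosomal genes (0 of 35) had no call by limma, and 2 of 7 bone and 1 of 9 macrophage markers rose. With the block 3, 2, 3, 0, 0 and 1 of those 6 groups rose, and 1 muscle gene fell. Of 21 writers and other erasers of H3K4 methylation 1 rose (mean -0.03), of 23 glycolysis genes 1 rose and 3 fell, and 1 of 14 heat shock genes fell.

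Over all genes, 1218 were called at day 2, 766 up and 452 down. The highest were Plekha6 (3.37, SE 0.39), Angpt2 (3.14, SE 0.33), the transporter Slc22a18 (3.08, SE 0.35), Lsp1 and Col23a1. Among the lowest were Retnla (-2.06, SE 0.33), Tgm2, Wfdc21 and Elovl1 (-1.63, SE 0.19). With the replicate block 3809 were called, 1885 up and 1924 down, and 25 with only the compared groups. The number was 488 without shLuc replicate 1, 213 without shLuc replicate 2 and 165 without shKdm5ABC replicate 1.

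**Figure D3:**
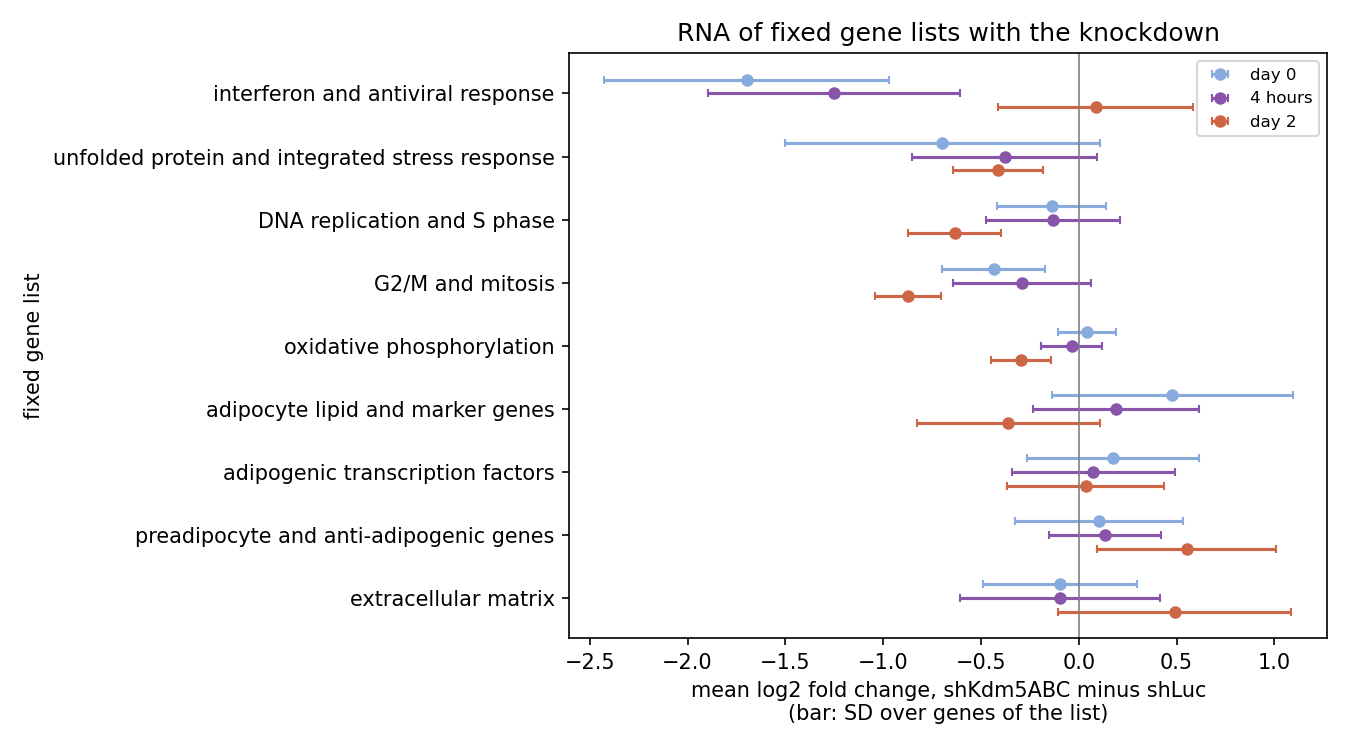
Mean log2 fold change (shKdm5ABC minus shLuc) of 9 fixed gene lists at day 0, 4 hours and day 2, with bars for the SD over the genes of a list. The mitosis mean was -0.43, -0.29 and -0.87 at the 3 times, and the interferon mean -1.70, -1.25 and 0.09.

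The knockdown effect itself differed between day 0 and day 2 in 42 genes by limma, 42 with a more positive log2 fold change at day 2 and 0 with a more negative one. Rsad2 (3.30, SE 0.44), Isg15 (2.10, SE 0.33) and Stat2 (1.61, SE 0.20) were among 7 interferon genes in that group, 25 adjusted over the list alone, and the matrix gene Fn1 had a difference of 1.47 (SE 0.22). For the interferon list the day 0 fall was gone at day 2 (list mean 0.086), so its difference was smaller there and not larger. By then the list had fallen in shLuc cells too, with Isg15 at 4.97 and 5.07 in the day 2 libraries. Whether the knockdown acts less at day 2 cannot be told from genes that had fallen this far. Apod (2.61, SE 0.39) and P2rx3 (2.42, SE 0.35) were among the highest of the 42. Over all genes 1617 had an unadjusted p under 0.05, and with the block 1038 were called, 644 up and 394 down. It was 0 by limma without a filter on low values (1935 with an unadjusted p under 0.05), 9 with only the compared groups and 24 without the mean-variance trend. The number was 0 without shLuc day 0 replicate 1, shLuc day 0 replicate 2, shLuc day 2 replicate 1, shKdm5ABC day 0 replicate 2 or shKdm5ABC day 2 replicate 1. It was 1 without shLuc day 2 replicate 2 or shKdm5ABC day 0 replicate 1, and 144 without shKdm5ABC day 2 replicate 2. Between day 0 and 4 hours limma called 0 genes (501 with an unadjusted p under 0.05, 8 with the block). The RNA table holds no counts for another tool.

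Most KDM5A tags in peaks lay at promoters, but most peaks did not. Peaks within 1000 bp of a start site were 13.2% of all 87525 peaks and 47.0% of the 20222 with at least 20 tags but held 67.4% of the tags in peaks, with a median of 162 tags against 6.42 elsewhere, and the input library had a median of 11.7 at the promoter peaks and 0.90 elsewhere. Of 10702 H3K4me3 promoter peaks 96.4% overlapped a KDM5A peak. Gins1, Rfc4 and Rpa1 had 532 (SD 214), 901 (SD 395) and 352 (SD 74.1) KDM5A tags at day 2. Of 50 replication genes 54.0% were in the top 25% of genes by KDM5A tags (odds ratio 3.54, adjusted p 2.89e-04), as were 66.7% of 21 writers and other erasers of H3K4 methylation (odds ratio 6.02, adjusted p 8.75e-04) and 58.6% of 29 oxidative phosphorylation genes (odds ratio 4.26, adjusted p 0.00104). Of 46 mitosis genes 30.4% were there (adjusted p 0.643). None of 30 interferon genes (0 of 30, Fisher's exact adjusted p 0.00253) and none of 23 adipogenic factors (0 of 23, adjusted p 0.0133) were. The median over interferon promoters was 84.4 tags at day 0 and 31.7 at day 2.

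**Figure D4:**
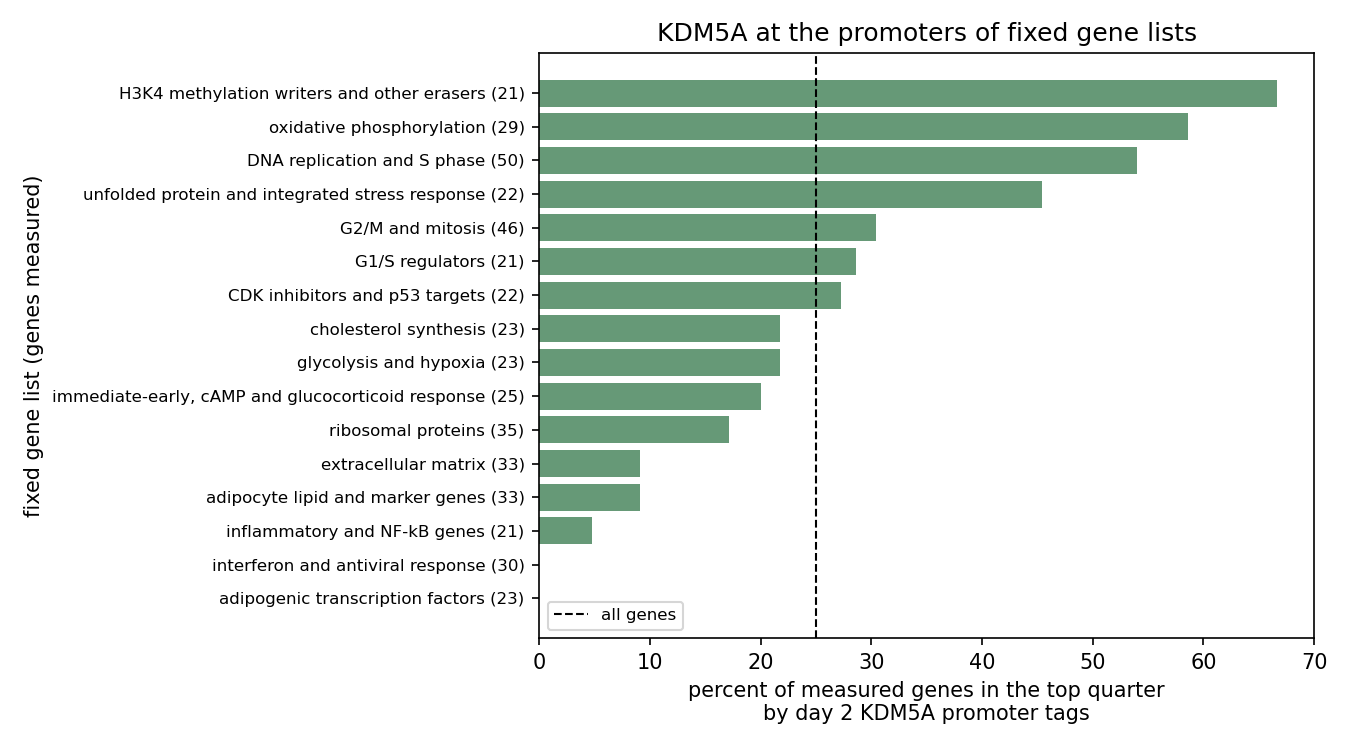
Percent of the measured genes of fixed lists (20 or more genes) in the top 25% of genes by KDM5A promoter tags at day 2, with a dashed line for all genes. Replication genes were at 54.0% and interferon genes at 0%.

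Few KDM5A peaks passed the test between times, and the libraries disagreed widely. A peak near Ankmy1 rose from 4.26 (SD 6.02) to 62.7 tags (SD 28.3) at 4 hours (log2 fold change 4.29, SE 0.75, adjusted p 4.00e-04), and a peak near Gm6567 rose by 3.50 (SE 0.75). At day 2 peaks near Prickle2 and Zfand6 were lower (-3.68 and -3.25, SE 0.71 and 0.75). The highest, near 4930455J16Rik, had a mean of 290 tags with an SD of 392, a spread that its p does not reflect. Between 4 hours and day 2 a peak 30638 bp from the start of Acsl1 rose by 4.53 (SE 0.83) among 531 called peaks, 108 up and 423 down. By limma 53 peaks were called at 4 hours, 53 up and 0 down, and 151 at day 2, 119 up and 32 down, while the simulated changes went unrecovered. By edgeR the numbers were 13 and 559, and with only the compared groups 3 and 284. The median of all peaks shifted by 0.18 at 4 hours and 0.37 at day 2. With medians set equal 113 were called at 4 hours (89 up, 24 down) and 1273 at day 2 (189 up, 1084 down), and with quantile normalization 193 (133 up, 60 down) and 822 (280 up, 542 down). At 4 hours 208 were called without day 0 replicate 1, 11 without day 0 replicate 2 and 0 by limma without 4 hour replicate 2 (3135 with an unadjusted p under 0.05). Without 4 hour replicate 1 the direction turned, with 6 up and 48 down. At day 2 51 were called without day 0 replicate 2, 0 without day 2 replicate 1 (1761 with an unadjusted p under 0.05) and 369 without day 2 replicate 2.

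Of 14827 KDM5C peaks at day 2, 6374 (43.0%, 95% interval 42.2% to 43.8%) overlapped a KDM5A peak. The share was 94.1% within 1000 bp of a start site and 34.2% elsewhere. For scale, 96.4% of H3K4me3 promoter peaks overlapped a KDM5A peak, so the promoter share is near that of promoters at large. KDM5A peaks covered 70.0 Mb in all. The 2 KDM5C libraries correlated at 0.296 across peaks (peaks are not independent replicates), with 3.49% and 1.47% of their tags in peaks. Among the 1212 peaks with at least 20 tags in each library 86.9% overlapped.

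Genes bound by KDM5A had lower RNA with the knockdown at day 2 than the rest. Gins1, Rpa1 and Rfc4 fell (by 1.04, 0.60 and 0.84), and among all 2644 bound genes 54 rose and 131 fell, against 712 and 321 of 10890 others (odds ratio 1.72 for a fall, exact p 8.90e-07, and 0.298 for a rise, exact p 2.62e-23). Their mean RNA change differed from that of the rest by -0.19 (camera p 1.10e-05, 0.00505 with an estimated correlation). The gap was smaller against random lists matched on RNA level and drawn from all genes, bound ones included, as the bound mean was -0.095, the mean of these lists 0.0084 and that of the rest 0.091. With any overlapping peak as the definition of bound the difference was -0.051 (p 0.338), and with quantile normalization it was -0.089 (p 0.0199). At day 0 and 4 hours bound genes were not called lower more often than the rest, though their means lay below those of matched lists. Means of bound genes and lists were -0.026 and -0.010 at day 0, and -0.023 and -0.0089 at 4 hours. The bound mean lay at percentile 0.05 and 0.32 of the lists at these times, and at 0 at day 2. The odds ratios for a fall were 0.711 (exact p 0.207) and 0.594 (exact p 0.134), those for a rise 0.210 (exact p 2.23e-04) and 0.198 (exact p 1.33e-05), and the mean differences -0.059 (camera p 0.0969) and -0.063 (camera p 0.142). In shLuc cells the same genes changed from day 0 to day 2 by 0.47 relative to the rest (camera p 2.04e-06, 0.00349 with an estimated correlation). The random lists were not matched on this change, so a general damping of the day 2 changes was not set apart from binding.

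H3K4me3 was measured at promoter peaks in 12 libraries, and its values moved with the column order of the table. In the libraries labelled shLuc day 0, 66.9% and 65.6% of tags lay in promoter peaks, followed by 80.5% and 81.3% (labelled shLuc 4 hours), 67.0% and 66.9% (shLuc day 2), 83.2% and 80.7% (shKdm5ABC day 0), 68.1% and 66.2% (shKdm5ABC 4 hours) and 80.0% and 78.8% (shKdm5ABC day 2). The promoter of Plin1, which coats lipid droplets, had 8.39 tags in the libraries labelled shLuc day 0, 11.2 in those labelled shLuc day 2 and 126 in those labelled shKdm5ABC 4 hours. Adipoq had 13.0, 17.4 and 168. Across 9954 genes the labelled change from day 0 to 4 hours in shLuc had a rank correlation of -0.0962 with the RNA change, and from day 0 to day 2 it was 0.449 (genes are not independent replicates).

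**Figure D5:**
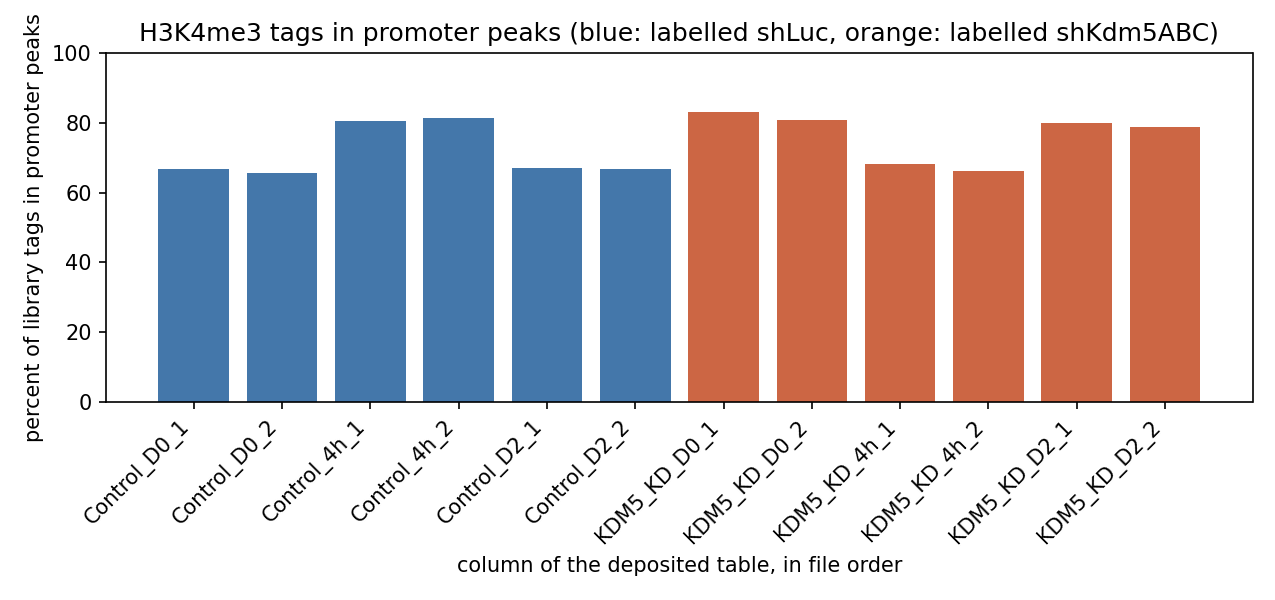
Percent of library tags in H3K4me3 promoter peaks for each of the 12 columns in file order, coloured by the labelled shRNA. Shares alternate by pairs between 65.6% to 68.1% and 78.8% to 83.2%.

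Between the libraries labelled shKdm5ABC and shLuc, promoter signal was higher at day 0 and day 2 and lower at 4 hours. These directions, that at 4 hours above all, rest on the column labels, which the values above put in doubt. Under another column order, described below, each labelled comparison would set shKdm5ABC and shLuc at different times against each other. Lsp1 had 79.4 tags in libraries labelled shLuc and 1017 in those labelled shKdm5ABC at day 0 (log2 fold change 3.65, SE 0.30, adjusted p 1.62e-04), and Ifit1 fell by 1.21 (SE 0.25). At 4 hours Plin1 and Fam83a were higher (4.37 and 4.20, SE 0.38 and 0.35) and Apol9a lower (-5.58, SE 0.44). At day 2 the complement gene C3 was higher (4.62, SE 0.30), as was Cdc20 (296 and 680 tags, adjusted p 0.00224), while Plaur was lower (-0.93, SE 0.24). By limma 3520 of 10702 peaks were called at day 0, 3499 up and 21 down, 3839 at 4 hours, 173 up and 3666 down, and 2571 at day 2, 2545 up and 26 down. The median of all peaks shifted by 0.29, -0.23 and 0.25. With medians set equal the calls were 1140 (1014 up, 126 down), 3478 (990 up, 2488 down) and 832 (752 up, 80 down). With quantile normalization they were 784 (571 up, 213 down), 2819 (1231 up, 1588 down) and 486 (390 up, 96 down). With the replicate block they were 6470, 6231 and 5683.

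The number at day 0 was 1463 without the library labelled shLuc replicate 1 and 1626 without shKdm5ABC replicate 1. At day 2 it was 1076 without shLuc replicate 1, 1613 without shLuc replicate 2, 1260 without shKdm5ABC replicate 1 and 1223 without shKdm5ABC replicate 2. In the libraries labelled shLuc, Vdr, the vitamin D receptor gene, had 485 tags at day 0 and 2616 at day 2 (log2 fold change 2.42, SE 0.13), while Ifit3 fell by 2.06 (SE 0.40). There 211 peaks were called at day 2, 140 up and 71 down (1651 with the block, 42 with only the compared groups), and 2981 at 4 hours, 2980 up and 1 down (6350 with the block, 274 with only the compared groups), with Lsp1 (79.4 and 1000 tags, SE of the log2 difference 0.30) the highest and Rtp4 (-0.59, SE 0.18) the lowest. With medians set equal 525 were called at 4 hours (512 up, 13 down) and with quantile normalization 241 (223 up, 18 down). At 4 hours 847 were called without shLuc day 0 replicate 1 and 1428 without shLuc 4 hour replicate 2. At day 2 38 were called without shLuc day 0 replicate 1, 97 without shLuc day 0 replicate 2, 24 without shLuc day 2 replicate 1 and 105 without shLuc day 2 replicate 2.

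The labelled knockdown effect on H3K4me3 differed between day 0 and day 2 at 82 peaks, 12 up and 70 down (1268 with the block), Gm11978 among them (-5.28, SE 0.35). With quantile normalization 125 were called (32 up, 93 down). The number was 38 without the library labelled shLuc day 0 replicate 1, 37 without shLuc day 2 replicate 1, 32 without shKdm5ABC day 0 replicate 1, 42 without shKdm5ABC day 2 replicate 1 and 49 without shKdm5ABC day 2 replicate 2. At promoters bound by KDM5A the labelled day 2 change was -0.22 relative to the rest (camera p 0.148, 0.752 with an estimated correlation), and -0.014 (p 0.886) with quantile normalization. With any overlapping KDM5A peak as the definition of bound it was -0.87 (camera p 2.35e-07). That set held 10317 of 10702 promoters (96.4%), so the rest were few, and it was not matched on H3K4me3 level. At day 0 the labelled difference was -0.24 (camera p 0.103), and at 4 hours it was 0.50 (camera p 6.64e-10, 0.208 with an estimated correlation). Gaps were smaller against random lists matched on H3K4me3 level. Means of the bound promoters and of these lists were 0.217 and 0.227 at day 2, 0.236 and 0.283 at day 0, and -0.090 and -0.248 at 4 hours. The bound mean still lay at percentile 0.25, 0 and 100 of the lists. The day 2 difference from the rest was -0.31 without shLuc day 2 replicate 2 and -0.30 without shKdm5ABC day 2 replicate 1.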

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

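These tests were chosen only after the result was seen: the H3K4me3 difference at 4 hours minus day 0, the tests of column order, of H3K4me3 against RNA, of adipocyte promoters and of yield or scaling, the 3 tests on interferon genes, the comparison of bound members within lists, and the use of quantile normalization, itself a planned setting, as a test of the cell cycle fall.

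The knockdown effect at day 2 minus that at day 0 passed the test in 42 genes and at 82 H3K4me3 peaks as labelled, and at 4 hours minus day 0 at 5022 peaks. The same difference in list means was past the threshold for replication (-0.50, adjusted p 2.99e-13), mitosis (-0.44, adjusted p 6.50e-08), G1/S (-0.21, adjusted p 0.00988), adipocyte (-0.84, adjusted p 1.62e-06), preadipocyte (0.45, adjusted p 0.00837), matrix (0.59, adjusted p 6.82e-07), interferon (1.78, adjusted p 3.38e-28), inflammatory (0.53, adjusted p 3.36e-04), oxidative phosphorylation (-0.34, adjusted p 1.10e-08), glycolysis (-0.20, adjusted p 0.0170) and stress response genes (0.28, adjusted p 0.0170). With an estimated correlation none of these 11 lists was past it (adjusted p 0.225 to 0.476).

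The share of H3K4me3 tags in promoter peaks alternated from group to group in column order, and one hypothesis is that the columns carry group names in another order. Among all 720 ways to assign the 6 names, scored by the correlation of centred group means with RNA over 9954 genes, the labelled order ranked 227 (score 0.0828). The highest score (0.536, next 0.491) went to shLuc and shKdm5ABC in turn at day 0, then 4 hours, then day 2. In that order the column pairs with the higher tag shares are all shKdm5ABC and those with the lower shares all shLuc. The columns labelled shKdm5ABC and shLuc at 4 hours would then be shLuc day 2 and shKdm5ABC day 0. Those labelled shKdm5ABC day 0 would be shKdm5ABC 4 hours, and those labelled shLuc day 2 would be shLuc 4 hours. Each labelled comparison of shKdm5ABC with shLuc would thus mix times. That order was found from the same H3K4me3 values, so no groups were compared under it. Against the labels, the shLuc change to 4 hours correlated with RNA at -0.0962 and the adipocyte promoters had a median change of -0.0228 to day 2 while their RNA rose by 4.01, whereas the shLuc day 2 change correlated with its RNA at 0.449 but with the RNA change to 4 hours at 0.691. A shift shared by all peaks of a library is unlikely to explain all differences between columns as labelled shKdm5ABC and shLuc. With medians set equal or quantile normalization the number of calls was at least 18.9% of the first number. Whether the same peaks were called was not compared. Unequal yield that changes some peaks more than others may remain under both settings, so it cannot be told apart. Some calls were new, as 96 peaks were down at day 2 with quantile normalization against 26 in the main fit. For shLuc day 0 to 4 hours the numbers were 17.6% and 8.08% of the first, and there a scaling cause cannot be told apart.

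Interferon genes were lower with the knockdown at day 0. A single library is unlikely to make the difference, since the list mean was -1.38 or lower without any of the 4. The shLuc virus may have drawn a stronger antiviral response than the knockdown virus: at day 2 the list mean was 0.086, but there is no untransduced RNA sample, so the 2 cannot be told apart. Strong KDM5A binding at these genes is unlikely in the samples where it was measured, as 3.33% of them (1 of 30) were in the top 25% by day 0 promoter tags. No transduction is stated for those samples, there is no KDM5B ChIP, and KDM5C ChIP covers day 2 only. A direct route through the 3 proteins in the transduced cells therefore cannot be judged. Weaker binding stays open, since 80.0% had a promoter peak against 73.9% of all genes.

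Cell cycle genes were lower with the knockdown at day 2. A general damping of the day 2 changes could lower any gene that rises. The 96 genes had a mean of -0.75 and lists matched on the day 2 change -0.34, a difference of -0.41. These means also hold any gap already present at day 0, when both cell cycle list means were lower with the knockdown too. From day 0 to day 2 the knockdown effect changed by -0.50 (replication) and -0.44 (mitosis), which was not set against matched lists. How much of the fall damping leaves unexplained therefore cannot be told. Whether members strongly bound by KDM5A fall more cannot be told apart: the pooled difference was 0.11 (31 and 65 genes, permutation p 0.0351), but the lists differ in both binding and fall. Within the lists it was 0.046 (permutation p 0.341), with 0.12 for replication (p 0.0744) and -0.084 for mitosis (p 0.181). Scaling is an unlikely cause, as the mitosis mean was -0.87 with quantile normalization.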

How the results depend on the processing

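The edgeR test and camera with an estimated correlation plus block were chosen after seeing the data. A group left with 1 library was assumed to vary like the others. Of the alternative values 134 stayed of similar size, which for counts does not mean the same calls, 96 moved a count, 9 were weaker, 4 stronger and 1 reversed. The cause was not tested. The RNA table holds no counts, so depth limits there are unknown. Calls from KDM5A, which has 3 residual degrees of freedom and libraries down to 3.87M tags, are the least certain. In the main KDM5A fit the spread of a single peak did not enter its p. edgeR shares the library totals, so it bears on the error model alone.

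With only the compared groups, RNA knockdown counts were 11, 0 (1342 with an unadjusted p under 0.05) and 25, the day 2 minus day 0 difference 9, H3K4me3 in shLuc 274 (4 hours) and 42 (day 2), and KDM5A 3 and 284. With a fold change of at least 1 on the log2 scale RNA counts were 126, 117 and 486 for the knockdown and 2401 and 3997 for time, and H3K4me3 1073, 1844 and 803 for the knockdown and 838 and 84 for time. With the replicate block RNA counts were 1277, 1310 and 3809, and 1038 and 8 for the differences, H3K4me3 6470, 6231 and 5683, 6350 and 1651 for time and 1268 for the difference, and KDM5A 720 and 840. KDM5A replicates paired at 0.0470 to 0.333. Without a filter the RNA differences were 0 (limma, 1935 with an unadjusted p under 0.05) and 4, and without the trend 24.

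With medians set equal H3K4me3 counts were 1140 and 832 (knockdown, day 0 and day 2) and 525 (shLuc, 4 hours), and KDM5A 113 and 1273. With quantile normalization they were 784, 486, 241 and 125 (difference), and 193 and 822. KDM5A counts were 16 and 294 with a pseudocount of 10, 118 and 81 with at least 20 tags, and 13 and 559 with edgeR.

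Leaving out 1 library gave RNA knockdown counts of 13 to 72, 11 to 36 and 165 to 970, time counts of 4144 to 4405 and 6119 to 6296, and differences of 0 to 144 and 0 to 0. H3K4me3 gave 1463 to 2702, 2718 to 3404, 1076 to 1613, 847 to 2071, 24 to 105 and 32 to 75, and KDM5A 0 to 208 and 0 to 369. List means ranged from -0.77 to -0.50 (replication), -0.92 to -0.83 (mitosis), -0.0057 to 0.076 (adipogenic factors) and -0.69 to -0.032 (adipocyte), and bound sets from -0.31 to -0.12 (H3K4me3) and -0.20 to -0.17 (RNA).

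With an estimated correlation the replication (-0.63), mitosis (-0.87) and adipocyte (-0.36) lists had adjusted p 0.155, 0.214 and 0.627, and with the block as well 0.321, 0.325 and 0.448. The H3K4me3 difference at bound promoters was -0.87 (camera p 2.35e-07) with any overlapping peak, a set of 96.4% of promoters. It was -0.23 (camera p 0.0456) by day 0 tags, and the RNA difference was -0.051 (camera p 0.338) with any peak. The KDM5C overlap was 39.4% over at least 0.5 of the peak length, 86.9% with at least 20 tags and 22.0% for centres within 200 bp.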

Other observations

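KDM5A at promoters of interferon genes was lower at day 2 than at day 0, relative to other promoters. Over 23 interferon genes the median log2 change in KDM5A tags was -0.34, against 0.29 over 9741 genes, and 21 of the 23 lay below the overall median. The overall value rests on a low day 0 library: the median at promoter peaks was 209 and 92.0 tags in the day 0 libraries and 209 and 157 in those of day 2. Ifit3, whose RNA fell by 7.16 over the same interval in shLuc cells, had 18.8 KDM5A tags at its H3K4me3 peak at day 0 and 2.30 at day 2. This test was chosen after the pattern was seen, with its prediction written before its outcome was computed. The change in KDM5A tags had a rank correlation of 0.238 with the shLuc RNA change across genes, which are not independent replicates. The hypothesis that KDM5A occupancy moves with RNA may hold, though open chromatin could give the same value of 0.238. The RNA came from transduced cells, while no transduction is stated for the KDM5A samples. Whether interferon RNA was as high at day 0, or fell, in the cells of the KDM5A samples was not measured.

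Input signal was high around Mdm2, which encodes the ubiquitin ligase that degrades p53. The promoter peak of Mdm2 had 310.59 input tags and a mean of 2848 KDM5A tags, and its RNA level was 13.2 on the log2 scale. Over 87525 peaks the median input was 1.80 tags per kb and the 99.9th percentile 18.7. Of the 88 peaks above that, 14 lay on chromosome 10 between 116.387 and 117.58 Mb, a stretch of 32 peaks that also holds Cpsf6, Frs2, Nup107 and Rap1b. No test of this was made.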
